A study of Mus musculus with 8 samples.

How the data were processed

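RNA was sequenced from OT-I CD8 T cells edited with a guide RNA against LacZ (4 control libraries) or against Carm1 (4 Carm1-edited libraries). Groups were taken from the source names in the labels, and replicate numbers from the titles. Per the labels' protocols, naive CD8 T cells were isolated from spleen and inguinal lymph nodes by negative selection, cultured with 2.5 ng/ml interleukin-7 and 50 ng/ml interleukin-15, and edited by nucleofection. RNA was taken 7 days later, had an integrity number above 9.5, and was made into libraries with a poly(A) TruSeq kit that does not mark strand, with paired 150 bp reads on a NextSeq 500. The guide sequences and the position of the edit are not given in the sources used here.

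The deposited files hold whole-number counts per Ensembl gene, with the exons and length of each gene, and the authors obtained them with RSEM on mm10, per the labels' protocols and the submitters' processing notes. RSEM gives expected counts that need not be whole, and the column layout of the files is that of another kind of counting program, so how whole numbers arose is not known. The aligner, annotation release, strand setting and all versions are not given in the sources used here. Reads shared by similar genes could have been split or dropped in that step. The counts were used as deposited, with no rounding. Of 49315 gene identifiers, 48970 were given a symbol from the GENCODE M21 annotation of GRCm38, the assembly of mm10. All 8 files listed the same genes, and no line lacked a gene identifier. Identifiers without a symbol held 0.0269% to 0.0535% of the counts.

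Replicates were compared before they were averaged. A chi-square test over genes with at least 20 counts in a pair gave 1.45 to 13.5 per degree of freedom for the 12 pairs within groups, where sampling noise alone gives about 1, so no library was counted as a copy of another. Between groups it was 418 to 447. The labels call these libraries technical replicates and do not give the number of cultures or animals per arm, so the spread between them may leave out the variation between cultures or animals.

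Genes were kept by edgeR's filterByExpr with its defaults (14970 genes), scaled with TMM factors (0.938 to 0.953 in control and 1.05 to 1.07 in Carm1-edited libraries), and tested by robust quasi-likelihood F tests (edgeR 4.0.16, two-sided, R 4.3.3) with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of F. CPM are counts scaled to a common total, on TMM-scaled library sizes. Folds of genes with more than 3 counts in each group are fitted. With 0 counts in a group the fold is a bound against 3 counts over that group, and with 1 to 3 counts it is a ratio of the groups' summed counts with a 95% exact binomial (Clopper-Pearson) interval. Such bounds, ratios and intervals are on library totals without TMM factors and cover counting error only. Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 41 lists with at least 3 tested members. Of the lists so called, 0 were called with an estimated correlation, with adjusted p from 0.055 to 0.35, and 12 of the 41 lists had an unadjusted p under 0.05 there. Library-level shares were compared by exact two-sided permutation tests (scipy 1.17.1), adjusted over 6 measures.

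The gene lists of the comparison, its tests, the alternatives and the rule for naming genes were fixed before the data were examined. The held-out lists and several tests of explanations came later. The rule took Carm1, a panel of 20 T cell genes regardless of result, the 12 largest rises and 12 largest falls among genes that passed, had a mean of at least 2 CPM and did not overlap between groups (leaving out predicted genes and identifiers without a symbol), up to 4 members per list with the smallest adjusted p, and the 2 most abundant members per list of markers of other cell types. It named 173 genes, and the text names part of them. Some single genes are not reported here.

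Alternatives were RLE (relative log expression) and upper-quartile factors, library totals alone, no filter or a filter of at least 5 CPM in at least 4 libraries, DESeq2 1.42.0, limma-voom, a test against a 1.5-fold change, the replicate number as a block, mitochondrially encoded genes left out, each library left out in turn, and for lists an estimated correlation and fry. Other splits of the 8 libraries, 35 in all, were tested with the edgeR model.

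The edgeR step was tested on simulated counts for 14970 genes with 200 changed, drawn from the control means, library sizes and fitted dispersions of the comparison of Carm1-edited with control libraries. It recovered 70%, 76%, 86% and 96% of genes changed 1.25-, 1.5-, 2- and 4-fold, 50 of each, and called 10 of 14770 unchanged genes. Camera called 2 of 2 changed lists in the right direction and 0 of 20 unchanged lists. The simulated genes were drawn independently of each other, and 200 of 14970 were changed, whereas 87.7% of tested genes passed in the comparison. The simulation therefore does not test camera under correlation between genes, or scaling where most genes differ. Gene GC content and length came from the annotation and the files. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for tables and figures.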

Results

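Polyadenylated RNA was sequenced from OT-I CD8 T cells, mouse cytotoxic T cells that carry a transgenic receptor for an ovalbumin peptide, after CRISPR-Cas9 editing. The guide RNA was against Carm1 or, as the control, against the bacterial gene LacZ. Carm1 encodes an arginine methyltransferase that acts as a transcriptional coactivator. There were 4 control libraries and 4 Carm1-edited libraries, each with counts for 49315 genes. Total counts ran from 38768760 to 41439998 in the control libraries and from 37556330 to 39988442 in the Carm1-edited libraries, where 3 counts in a library corresponded to 0.0724 to 0.0799 CPM (counts scaled to a common library total). The labels call the 4 libraries of each arm technical replicates, so p-values measure only the spread between these libraries. The edit cannot be told apart from any other difference between the cell preparations. The series text describes co-culture of both arms with B16F10 melanoma cells expressing ovalbumin, while the sample protocols describe culture in interleukin-7 and interleukin-15 and RNA from cells collected 7 days after editing. Levels below are CPM scaled by TMM factors, as mean ± SD with n = 4 per group, and log2 fold changes are Carm1-edited minus control with their standard error (SE).

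The edited gene was measured first, as a partial check of the labels. Carm1 (ENSMUSG00000032185, chromosome 9, 21546894 to 21592623, plus strand, mm10) fell from 95.9 ± 1.04 CPM in the control libraries to 32.8 ± 0.493 CPM in the Carm1-edited libraries. The log2 fold change was -1.55 ± 0.027 (edgeR quasi-likelihood test, adjusted p = 1.6e-37), and all 4 edited libraries lay below all 4 control libraries. Such a fall was common here. Of 14970 genes tested, 2279 passed and were at least 2-fold lower, and 12481 did not overlap between the groups. The RNA is therefore a weak check of the edit. The count covers the whole gene, an edit that shifts the reading frame need not remove the RNA, and loss of the protein was assessed by the authors by western blot, per the labels' protocols.

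The comparison asks which transcripts differ between Carm1-edited and control T cells. Transcripts of the early memory regulators Tcf7 and Myb and of the inhibitory receptors Lag3 and Tigit were higher in the Carm1-edited libraries, while those of the effector molecules Gzmb, Ifng and Tnf and of DNA replication genes were lower. The wider lists were mixed, with 14 of 24 naive, memory and stem-like T cell genes and 12 of 18 cytotoxic granule and killing genes rising, 9 and 5 falling, and neither list called different. Such counts weigh each gene alike, and the 12 include the similar granzyme genes Gzmd, Gzme, Gzmf and Gzmg, at 2.64 CPM or less. Tcf7, which encodes a transcription factor of naive and stem-like T cells, rose 4.31-fold, and Ifng, which encodes interferon gamma, fell from 133 ± 3.19 to 0.527 ± 0.18 CPM. Of 14970 genes tested, 6667 were higher and 6468 were lower in the Carm1-edited libraries at an adjusted p under 0.05, together 87.7% of those tested. At least 2-fold differences were found for 3068 genes higher and 2279 genes lower, and at least 4-fold differences for 1323 and 755. The libraries of the groups did not overlap for 12481 genes, where chance gives 2.86% of genes for 4 against 4. The first principal component held 94.6% of the variance and parted the groups. Of the passing genes, 50.8% were higher with TMM factors and 61.0% with upper-quartile factors, which moved the median log2 fold change of all tested genes by 0.215, and library totals alone moved it by 0.160.

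**Figure D1:**
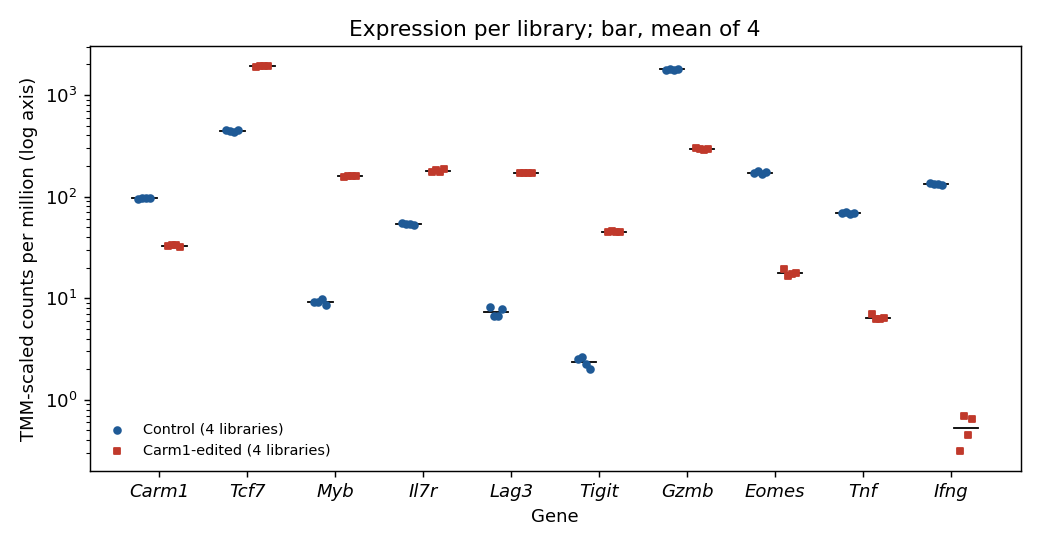
TMM-scaled CPM on a log axis for 10 genes in each of the 4 control libraries (circles) and 4 Carm1-edited libraries (squares), with bars at the mean of 4. Carm1, Gzmb, Eomes, Tnf and Ifng lie lower in every Carm1-edited library, and Tcf7, Myb, Il7r, Lag3 and Tigit lie higher, with Tcf7 at means of 445 and 1920.

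Among 24 tested genes of naive, memory and stem-like T cells, 14 rose, 9 fell and 1 did not pass (the same counts adjusted over the list alone). The list as a whole was not called different (camera, adjusted p = 0.25). Tcf7 rose from 445 ± 6.32 to 1920 ± 20.8 CPM (log2 fold change 2.11 ± 0.021). Myb, a transcription factor of stem-like CD8 T cells, rose from 9.19 ± 0.447 to 160 ± 1.78 CPM, a 17.3-fold difference. Il7r, the interleukin-7 receptor alpha chain, rose 3.32-fold. Id3, an inhibitor of E-protein transcription factors, rose 2.16-fold, and S1pr1, a receptor for exit from lymphoid tissue, rose 1.97-fold. Against these, Bcl2, which encodes a survival factor, fell 7.53-fold, and Igfbp4, an insulin-like growth factor binding protein, fell 18.1-fold. Eomes, a T-box transcription factor gene of the same list, fell 9.73-fold. Klf2, a quiescence-associated transcription factor, was at 180 ± 8.52 and 149 ± 14.3 CPM (log2 fold change -0.28 ± 0.076, adjusted p = 0.012), a call that was lost with upper-quartile factors (adjusted p = 0.47), library totals alone (0.17) and the replicate number as a block (0.069), in a range of 0.00020 to 0.47 over the alternatives.

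Effector genes moved in both directions. Gzmb, which encodes the protease granzyme B, fell from 1788 ± 20.5 to 294 ± 6.46 CPM (log2 fold change -2.60 ± 0.022, adjusted p = 3.3e-48), and Prf1, the pore-forming protein perforin, fell 2.99-fold. The T-box transcription factor genes Eomes and Tbx21 also fell, 9.73-fold and 1.43-fold. Tbx21 is in the list of effector regulators, whereas Eomes is in that of naive, memory and stem-like genes. Klrg1, a receptor of terminal effector cells, fell from 4.53 ± 0.537 to 0.202 ± 0.0753 CPM. In contrast, Serpinb6b, a serpin, rose 13.5-fold, and Cst7, which encodes the protease inhibitor cystatin F, rose 4.37-fold. The killer-cell lectin-like receptors Klrd1 and Klrk1 rose 16.9-fold and 6.46-fold. Of the 18 cytotoxic granule and killing genes 12 rose and 5 fell. The 12 include Gzmd, Gzme, Gzmg and Gzmf, at only 2.64, 0.930, 1.87 and 0.453 CPM in the Carm1-edited libraries. Of the 19 effector regulators and surface genes 8 rose and 10 fell, with the same counts adjusted over the list alone. Neither list was called different as a whole (camera, adjusted p = 0.14 and 0.73). Granzymes and killer-cell lectin-like receptors are families of similar genes, whose counts are uncertain where reads could be shared.

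Cytokine and chemokine genes were lower in the Carm1-edited libraries, with 14 of 17 tested members falling and 3 rising, also when adjusted over the list alone. Camera gave an adjusted p = 0.025, and adjusted p = 0.15 with an estimated correlation. For each of the 18 lists called, the estimated correlation gave the highest adjusted p over the camera alternatives. The lowest ones ran from 9.6e-18 for S phase genes to 0.038 for B cell markers. Ifng fell 251-fold, Cxcl10, an interferon-induced chemokine, fell 146-fold and Lta, which encodes lymphotoxin alpha, fell 13.1-fold. Tnf, which encodes tumour necrosis factor, fell from 69.3 ± 1.29 to 6.44 ± 0.351 CPM. Activation-induced early genes followed, with 16 of 24 falling and 8 rising, also when adjusted over the list alone. For this list camera gave an adjusted p = 0.040, and adjusted p = 0.15 with an estimated correlation. The AP-1 transcription factor genes Fos and Jun fell 177-fold and 7.06-fold, and the activation receptors Tnfrsf9 and Cd69 fell 4.64-fold and 4.03-fold. In the same comparison the myeloid marker Lyz2 was at 83.1 ± 1.36 CPM in the control and 0.148 ± 0.114 CPM in the Carm1-edited libraries.

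Inhibitory receptor and exhaustion genes were higher, with 14 of 20 tested members rising, 5 falling and 1 not passing, also when adjusted over the list alone. The camera adjusted p was 0.033, and adjusted p = 0.26 with an estimated correlation. Lag3 rose from 7.33 ± 0.804 to 171 ± 1.16 CPM (log2 fold change 4.54 ± 0.038), Tigit from 2.36 ± 0.279 to 45.2 ± 0.213 CPM, and Ctla4 7.02-fold, all of which encode receptors that dampen T cell activation. Ikzf2, which encodes the transcription factor Helios, rose 7.99-fold, Tox, a regulator of exhausted T cells, rose 2.18-fold, and Pdcd1, which encodes PD-1, rose from 4.21 ± 0.323 to 8.15 ± 0.289 CPM. Havcr2, which encodes TIM-3, rose but stayed low, at 1.08 ± 0.133 CPM. The call on the list was lost with upper-quartile factors (adjusted p = 0.072) and with library totals alone (adjusted p = 0.062). In the same libraries Cd79b, a B cell receptor component, was at 5.71 ± 0.248 and 17.1 ± 0.886 CPM, while Igkc, the immunoglobulin kappa constant gene, was at 17.5 and 0.306 CPM.

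Genes of the cell cycle moved apart. All 29 tested S phase and DNA replication genes fell, with a median log2 fold change of -2.05, while 25 of 26 G2/M and mitosis genes rose and 1 fell, with a median of 1.27. Both counts were the same adjusted over the list alone. The helicase subunits Mcm5, Mcm2 and Mcm3 fell 10.2-fold, 9.14-fold and 6.23-fold, and Uhrf1, which maintains DNA methylation at replication, fell 7.68-fold. In the other direction Cenpa, the centromeric histone, rose from 14.2 ± 0.895 to 112 ± 3.03 CPM. Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, rose 7.51-fold, Ccnb2, which encodes cyclin B2, rose 6.65-fold and Mki67, the proliferation marker Ki-67, rose 2.57-fold. Camera called the S phase list lower (adjusted p = 6.0e-10, and adjusted p = 0.068 with an estimated correlation) and the G2/M list higher (adjusted p = 9.0e-07, and adjusted p = 0.055 with an estimated correlation). Myeloid Lyz2 (83.1 and 0.148 CPM) fell and the B cell marker Cd79b (5.71 and 17.1 CPM) rose in the same libraries.

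All 25 MYC target and ribosome biogenesis genes fell, with a median log2 fold change of -2.16 (camera adjusted p = 3.4e-09, and adjusted p = 0.078 with an estimated correlation). Mybbp1a, Nolc1 and Nop56, which encode nucleolar proteins, fell 7.31-fold, 5.67-fold and 5.28-fold, and Cad, an enzyme of pyrimidine synthesis, fell 5.60-fold. Among RNA splicing factor genes 20 of 26 fell and 6 rose, Srsf7 4.43-fold and Hnrnpd 4.18-fold lower among them (camera adjusted p = 0.0012, and adjusted p = 0.26 with an estimated correlation). Among heat shock genes 12 of 16 fell, 3 rose and 1 did not pass, with the chaperones Hsph1 and Hsp90aa1 5.79-fold and 5.21-fold lower (camera adjusted p = 0.0035, and adjusted p = 0.15 with an estimated correlation). Of 22 unfolded protein response genes 21 fell and 1 rose (camera adjusted p = 1.8e-06, and adjusted p = 0.078 with an estimated correlation). Hspa5, the main chaperone of the endoplasmic reticulum, fell from 1084 ± 5.89 to 198 ± 4.63 CPM, and Xbp1, a transcription factor of this response, fell 4.05-fold. These counts were the same adjusted over the list alone. The myeloid marker Lyz2 fell in the same libraries, from 83.1 to 0.148 CPM.

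Glycolysis and nuclear-encoded oxidative phosphorylation genes were lower as well. Of 22 glycolysis genes 16 fell and 6 rose, with Hk2, a hexokinase, 6.31-fold and Slc2a1, a glucose transporter, 5.23-fold lower (camera adjusted p = 0.010, and adjusted p = 0.35 with an estimated correlation). Eno1, an enolase, was at 3888 ± 64.3 and 981 ± 11.4 CPM. Of 36 nuclear-encoded oxidative phosphorylation genes 33 fell, 1 rose and 2 did not pass, with a median log2 fold change of -0.58 and Ndufa4, a respiratory chain subunit, 3.62-fold lower (camera adjusted p = 1.8e-06, and adjusted p = 0.35 with an estimated correlation). Of the 13 mitochondrially encoded genes 9 rose and 3 fell (camera adjusted p = 0.22 for the list). They included mt-Co1, a cytochrome c oxidase subunit, at 2875 ± 30.9 and 7072 ± 106 CPM and mt-Cytb, the cytochrome b gene, at 910 ± 9.21 and 627 ± 3.78 CPM. The share of all counts in mitochondrially encoded genes was 0.604% ± 0.00804 in the control and 1.11% ± 0.0184 in the Carm1-edited libraries. An exact two-sided permutation test (n = 4 each) gave p = 0.0286, the smallest that 4 against 4 allows, and an adjusted p = 0.0343 over 6 library measures. Most of the rise in this share lay in mt-Co1. The median log2 fold change of the 13 genes was 0.27, so the share does not stand for the list. The list counts were the same adjusted over the list alone. Among these libraries the myeloid marker Lyz2 was at 83.1 and 0.148 CPM.

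Of 32 type I interferon response genes 27 fell, 2 rose and 3 did not pass (camera adjusted p = 9.0e-07, and adjusted p = 0.055 with an estimated correlation). Oasl2, an antiviral enzyme-like protein, fell 143-fold and Isg15, a ubiquitin-like protein, fell 18.1-fold. Ifit3 and Ifit1, RNA-binding antiviral proteins, fell 34.6-fold and 10.7-fold. Ifit3 has a close copy, Ifit3b, that could share its reads. Of 23 STAT5 and common gamma chain response genes 18 fell and 5 rose (camera adjusted p = 0.0017, and adjusted p = 0.15 with an estimated correlation), with Cish, a feedback inhibitor of cytokine signalling, 8.88-fold and the kinase gene Pim2 5.69-fold lower. Both counts were the same adjusted over the list alone. Lyz2, a myeloid marker, differed in the same direction in these libraries, at 83.1 and 0.148 CPM.

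Among 25 p53 target genes 17 rose, 6 fell and 2 did not pass, also when adjusted over the list alone. The camera adjusted p was 0.040, and adjusted p = 0.15 with an estimated correlation. The call was also lost with upper-quartile factors (adjusted p = 0.056), with library totals alone (0.055) and without control replicate 2 (0.050). The antiproliferative genes Trp53inp1 and Btg2 rose 5.51-fold and 5.44-fold and Sesn1, a stress-induced regulator, 2.44-fold, while Aen, a p53-induced nuclease, fell 2.85-fold. Of the best-known members, which were chosen after their values were seen, Cdkn1a rose 1.17-fold and Mdm2 fell 1.11-fold, and on the log2 scale Mdm2 moved by less than the 0.215 by which scaling moved the median. In these libraries the B cell marker Cd79b was at 5.71 and 17.1 CPM and the myeloid marker Lyz2 at 83.1 and 0.148 CPM. Of 23 BCL2 family and apoptosis genes 11 rose and 11 fell, with Bmf, a pro-apoptotic BH3-only gene, rising from 3.93 ± 0.0744 to 100 ± 2.51 CPM and Bcl2 falling from 798 ± 8.23 to 106 ± 3.28 CPM (camera adjusted p = 0.998 for the list).

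**Figure D2:**
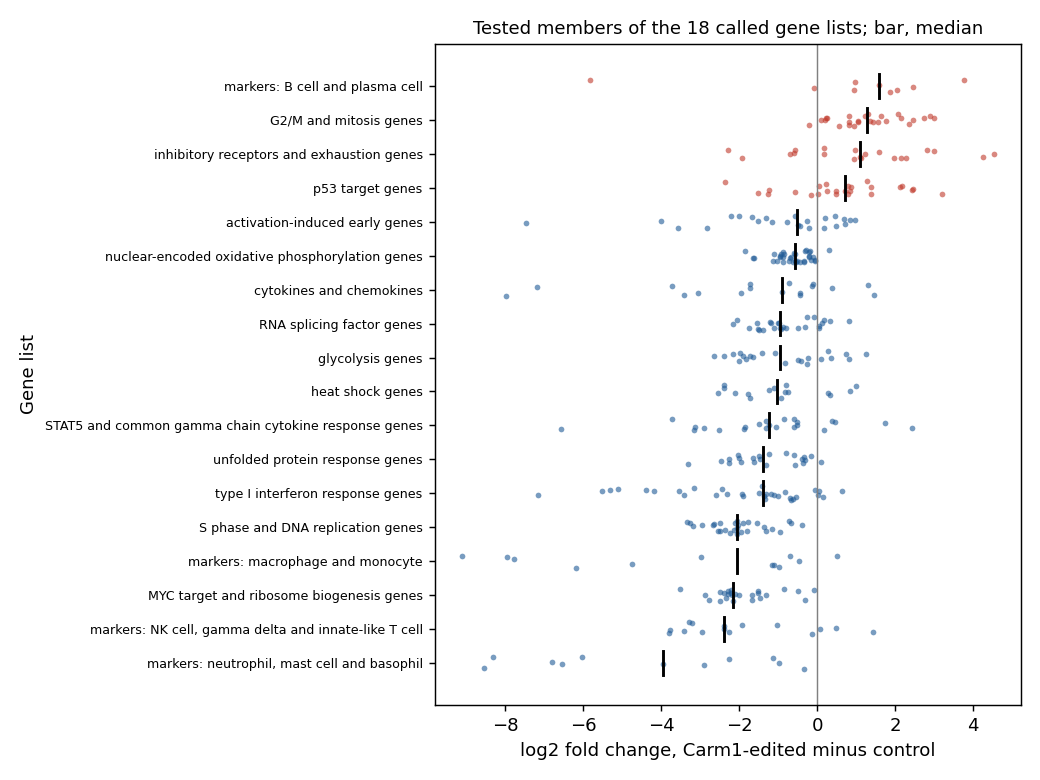
Log2 fold changes (Carm1-edited minus control, horizontal axis) of the tested members of the 18 gene lists that camera called with a preset correlation, one list per line on the vertical axis, with red points for the 4 lists called higher, blue points for the 14 called lower and a black bar at each median. The S phase points all lie below 0 around a median of -2.05, and the G2/M points lie above 0 except for 1, around a median of 1.27.

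The largest differences involved genes near 0 counts in one group. Ighg2b (chromosome 12, 113302965 to 113307933), an immunoglobulin heavy chain constant gene, Il1rn, the interleukin-1 receptor antagonist, and Cxcl9, a chemokine, had no counts in the 4 Carm1-edited libraries and were at least 417-fold, 239-fold and 231-fold lower, against 3 counts over the group. These bounds and the ratios below use library totals without TMM factors, unlike the CPM beside them. Chil1, a chitinase-like gene, was at 14.1 ± 0.342 CPM in the control and 0.0125 ± 0.0251 CPM in the Carm1-edited libraries, a ratio of 1032 with a 95% exact interval of 285 to 8524 that covers counting error. The other genes of this group were Ighg2c, Pla2g7, Lyz2, Clec7a, Acod1, Tnfaip2, Il1b and Hp, several of which are known from myeloid cells. Ighg2b and Ighg2c are similar genes, and their counts are uncertain. Among the largest rises, Gucy2e, a guanylate cyclase, was at 0.00682 and 5.29 CPM (ratio 884, 95% exact interval 158 to 34951). For Mgat3, a glycosyltransferase gene, the ratio was 668 (interval 228 to 3244). Zfyve28, Dnm1, Ltk, Fbxo2, Insrr, Wnt10b, Tspan2, Gpr162 and Ypel4 rose from under 0.5 CPM to between 5.14 and 35.8 CPM. Atcayos, antisense to Atcay, was also among them, at 0.0671 and 9.23 CPM, but the library kit named in the labels does not mark strand, so its reads cannot be told apart from those of Atcay.

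Markers of other cell types also differed. All 11 tested neutrophil, mast cell and basophil markers fell (camera adjusted p = 0.0028, and adjusted p = 0.078 with an estimated correlation), with the granulocyte enzyme gene Mpo at 11.9 ± 0.634 and 0.105 ± 0.0569 CPM. Of 12 macrophage and monocyte markers 11 fell and 1 rose (camera adjusted p = 0.011, and adjusted p = 0.17 with an estimated correlation), with Lyz2, which encodes lysozyme, 554-fold lower and Ctss, a lysosomal protease that T cells also express, 2.15-fold lower. Of 15 markers of NK, gamma delta and innate-like T cells 11 fell and 3 rose (camera adjusted p = 0.033, and adjusted p = 0.21 with an estimated correlation), with Eomes falling and Trdc, the T cell receptor delta constant gene, at 321 ± 5.42 and 339 ± 8.92 CPM. Of 9 B cell and plasma cell markers 7 rose and 1 fell (camera adjusted p = 0.047, and adjusted p = 0.21 with an estimated correlation), with Ighm, the immunoglobulin mu constant gene, at 254 ± 2.43 and 925 ± 10.5 CPM. The calls on the cytokine, macrophage and NK lists were lost with a filter of at least 5 CPM in 4 libraries (adjusted p = 0.076, 0.066 and 0.12). The call on B cell markers was lost with the same filter (adjusted p = 0.16), with no filter (0.093), with upper-quartile factors (0.090), with library totals alone (0.074) and with DESeq2 (0.12). Of 16 melanocyte and melanoma markers 6 were tested, 3 rose and 3 fell, with Pmel, a pigment-granule gene, at 3.42 ± 0.147 and 12.7 ± 0.563 CPM. The tyrosinase-family genes Tyr, Tyrp1 and Dct had 0 counts in all 8 libraries, which allows up to 3 counts over each group. Counts of these marker lists were the same adjusted over the list alone.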

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

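The tests of GC content and length, of the preparations, of library totals, of one scaling factor and of matched random lists were chosen after the results they bear on were seen.

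Most tested genes differed between the Carm1-edited and control libraries. Of the 35 splits of the 8 libraries into 4 and 4, 1, the real one, gave 13135 genes past the threshold, 5347 genes at least 2-fold apart and 18 gene lists called different, where the highest of the others gave 0, 0 and 16. Camera with an estimated correlation called 0 lists in the real split. Ranking first of 35 is the best rank possible, and the other splits mix the arms, so the difference between arms enters their spread. The ranking cannot exclude chance by itself, and technical replicates may leave out variation between cultures. The 16 lists came from splits of 3 libraries of one arm and 1 of the other against the rest, which keep part of the difference between arms and called 10 to 16 lists. Splits of 2 and 2 called 0 to 3. The count of lists thus hardly parts the real split from those of 3 and 1. Deciles of GC content and length explained 0.766% of the variance of the log2 fold changes, which argues against these biases as the cause. The first principal component held 94.6% of the variance and parted the arms, but the labels give no separate preparations within an arm, so the edit cannot be told apart from any other difference between the preparations.

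Transcripts of myeloid cells and granulocytes were higher in the control libraries. Mean library totals differed by a ratio of 1.02, so depth is not a likely cause. RNA of myeloid cells in the control culture is a candidate explanation. The negative selection for CD8 T cells is meant to remove such cells, but how completely it did so was not measured here. Of 32 tested held-out myeloid genes, 56.2% (18) were at least 2-fold lower in the Carm1-edited libraries, between the bounds set in advance. In all, 22 fell and 5 rose, with a median log2 fold change of -1.83, so RNA of myeloid cells cannot be told apart from a change within the T cells. Abundant markers fell unequally (Lyz2 from 83.1 to 0.148 CPM, Cd74 from 35.1 to 5.45, Apoe from 10.6 to 4.78 and Ctss from 175 to 81.1), Pld4 rose from 2.03 to 31.7 CPM, and 6 of 12 macrophage markers and 15 of 32 held-out genes were at 1 CPM or more in the Carm1-edited libraries, while 2 of the 12 are also in another list.

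S phase genes were lower and G2/M genes higher in the Carm1-edited libraries. One scaling factor would move both lists alike, but their medians differed by 3.32 on the log2 scale, and their middle ranges lay apart (-2.50 to -1.55 and 0.82 to 2.00). Of 10000 random lists matched on mean CPM, GC content and length, 0 had a median as low as the S phase list and 0 one as high as the G2/M list. Fewer cycling cells alone would lower both phases, but 28 of 29 held-out G2/M genes rose, with a median of 1.04. A shift of the cells within the cycle, linked to the edit or to another difference between the preparations, may explain this and was not tested.

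Groups of 4 libraries were examined for genes of the text and for library measures. In 20 of 292 such groups, all of genes, the highest or lowest library lay apart from the nearest. The gap was a share of the group's range above the 95% critical value of Dixon's test. Chance flags about 1 in 20 groups of normal values, a rate that does not hold for groups of 0 to a few counts. In the Carm1-edited libraries 1 library lay low for Bcl2 (0.835 of the range, at 101 CPM and the others up to 108), Cd74 (0.856, at 5.27), Cxcl10 (0.859, at 0.0251), Xist (0.867, at 172 and the others up to 196), Pmel (0.909, at 11.8) and Havcr2 (0.927, at 0.877). One of them lay high for Gbp2 (0.855, at 354), Tnf (0.874, at 6.96) and Cad (0.890, at 63.2). Of the control libraries 1 lay low for Cxcr6 (0.923, at 115 CPM), Gbp2 (0.925, at 2592) and Mgat3 (0.928, at 0). Likewise 1 of them lay high for Lta (0.886, at 170), Il1b (0.888, at 6.51) and Dnm1 (0.983, at 0.273). For Mgat3 the other control libraries were at 0.0253 to 0.0273 CPM, below the level of 3 counts, so its value reflects steps of whole counts. With the other 3 libraries at 0, the value was 1.0 for Chil1, Clec7a, Ighg2c and Pla2g7 in the Carm1-edited and for Gucy2e in the control libraries, where 1 library held the counts.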

How the results depend on the processing

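All alternatives here were planned, and no test here was chosen after its result was seen. Counts of genes stayed within 1.5 times their value except with a filter of at least 5 CPM, which tested 10171 genes and left 1543 at least 2-fold higher and 1270 lower, and in a test against a 1.5-fold change (glmTreat), which called 3992 higher and 3444 lower. DESeq2 called 7177 higher and 6974 lower. Gene lists called higher went from 4 to 2 with upper-quartile factors and to 2 with library totals alone, and lists called lower from 14 to 21 with no filter and with DESeq2 and to 10 with the stricter filter. Camera with an estimated correlation called 0 lists higher and 0 lower (12 at an unadjusted p under 0.05), while fry called 14 higher and 26 lower, since it asks whether a list moves one way and not whether it differs from other genes. Effector differentiation regulators and surface genes, with a median log2 fold change of -0.47, were not called by camera (adjusted p = 0.73) and were called higher by fry (adjusted p = 9.6e-06), and the cause was not tested. Leaving out each library in turn gave 6646 to 6712 genes higher, 6474 to 6568 lower, 3103 to 3220 at least 2-fold higher, 2336 to 2394 at least 2-fold lower, 3 to 4 lists higher, 14 to 16 lists lower and a Carm1 log2 fold change of -1.57 to -1.54. Antigen presentation and arginine methyltransferase lists became called without control replicate 1, 3 or 4 (adjusted p 0.046 to 0.050), the coactivator list without Carm1-edited replicate 3 (0.048), and p53 targets lost their call without control replicate 2 (0.050). With the replicate number as a block, 6611 genes were higher and 6420 lower, and 3 and 14 lists. Same-numbered libraries did not deviate together (correlations -0.0848 to -0.0509, none with its own number best), so the values show no sign of pairing by number. Klf2 and the B cell list lost their calls under the block. Among named genes over all settings, 2896 values kept direction and call, 12 lost their call (all of Klf2, H2-Ab1, Trdc or Prss34) and 0 reversed. Most of these genes were named for a small adjusted p or a large fold here, so their stability does not speak for other genes. Of the 13135 genes that passed, 12126 also passed with upper-quartile factors and 12251 with library totals alone. Low counts limit the markers near 0.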

Other observations

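The tests of the held-out lists were chosen after the first lists' results were seen, but before the held-out values were, and genes outside the fixed rule and the noncoding classes were chosen after their values were seen.

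Of 11 tested genes of the arginine methyltransferase list, which leaves out Carm1, 8 fell and 3 rose (camera, adjusted p = 0.053 for the list). Prmt7 was 4.16-fold, Prmt1, the main asymmetric methyltransferase, 3.81-fold, Prmt3 3.64-fold and Prmt5, the main symmetric one, 2.24-fold lower. Beside methyltransferases the list holds Wdr77 and Clns1a, which encode partners of Prmt5, and the F-box gene Fbxo11, so its counts are not those of the enzymes alone. That list was called with upper-quartile factors (0.022), library totals alone (0.029), no filter (0.0049), DESeq2 (0.014) and without control replicate 1, 3 or 4 (0.046 to 0.050), in a range of 0.0049 to 0.21 over the camera alternatives. Of 24 T cell receptor signalling genes 15 rose and 9 fell, among them Cd3g at 322 ± 5.64 and 678 ± 22.6 CPM, the coreceptor chain Cd8b1 at 768 ± 9.68 and 1348 ± 30.8 CPM and the phospholipase gene Plcg1 1.98-fold higher (adjusted p = 0.15). Of 18 fatty acid oxidation genes 11 rose and 6 fell, with Cpt1a, the carnitine palmitoyltransferase of the outer mitochondrial membrane, 4.42-fold higher (adjusted p = 0.23). Of 23 migration receptor and integrin genes 15 rose and 7 fell, with the chemokine receptor gene Cxcr3 7.70-fold higher, Cxcr5 rising from 3.31 to 46.6 CPM and Cxcr6 2.46-fold lower (adjusted p = 0.14). Of 20 TGF-beta response and tissue residency genes 8 rose and 11 fell, with Itgae, which encodes the integrin CD103, rising from 5.71 to 57.4 CPM (adjusted p = 0.52). Of 28 antigen presentation and interferon gamma response genes 18 fell and 9 rose, with the guanylate-binding protein gene Gbp2 at 2627 ± 23.7 and 341 ± 8.70 CPM and H2-Q6, an MHC class Ib gene with close copies and so uncertain, 2.74-fold higher (adjusted p = 0.059). This list was called with no filter (0.0025), DESeq2 (0.012) and without control replicate 1, 3 or 4 (0.046 to 0.050), in a range of 0.0025 to 0.33.

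The remaining lists were not called different at an adjusted p under 0.05 with the chosen settings, but some were under alternatives. With no filter and with DESeq2, lists called lower were ATF4 (adjusted p = 0.0071 and 0.024), hypoxia (0.0043 and 0.014), coactivator (0.0049 and 0.014), dendritic cell (0.0096 and 0.025) and erythroid (0.0055 and 0.021) genes. Ribosomal protein genes were called higher with upper-quartile factors (0.010), library totals alone (0.012) and the stricter filter (0.031). The highest adjusted p over the camera alternatives of these lists ran from 0.27 for dendritic and erythroid cells to 0.79 for ribosomal protein genes. ATF4 and integrated stress response genes had 15 of 25 lower and 7 higher (camera, adjusted p = 0.12), with the amino acid transporter gene Slc7a5 10.5-fold and Shmt2, a mitochondrial serine hydroxymethyltransferase, 6.20-fold lower. Hypoxia and HIF1 targets had 14 of 21 lower and 7 higher (0.069), NF-kB genes 12 of 20 lower and 7 higher (0.32), cholesterol genes 12 of 23 lower and 8 higher (0.23), coactivator and SWI/SNF genes 14 of 20 lower and 4 higher (0.067, and 0.048 without Carm1-edited replicate 3), ribosomal protein genes 24 of 40 higher and 9 lower (0.15) and canonical histone genes 4 of 8 lower and 2 higher (0.61), the last of these uncertain because the genes are near-copies of each other and mostly lack poly(A) tails. Markers of CD4 and regulatory T cells had 7 of 10 higher and 3 lower (0.31), of dendritic cells 8 of 12 lower and 4 higher (0.12), of erythroid cells and platelets 7 of 11 lower and 2 higher (0.14, median log2 fold change -4.16 fitted and -4.08 with members of 3 or fewer counts at the bound for 3 counts) and of fibroblasts 3 of 5 lower and 2 higher (0.55). These counts, like those above, were the same adjusted over the list alone. Median and mean differed in sign for the BCL2 family list, at 0.21 and -0.03, and for the CD4 and regulatory T cell markers, at 0.72 and -0.003.

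The granzyme genes Gzmd, Gzme and Gzmg had no counts in the control libraries and were at 2.64 ± 0.344, 0.930 ± 0.149 and 1.87 ± 0.257 CPM in the Carm1-edited libraries, and as close copies their separate values are uncertain. Immunoglobulin genes parted as well, with the kappa constant gene Igkc at 17.5 ± 0.674 and 0.306 ± 0.144 CPM while the heavy chain joining segment Ighj1 was at 1.74 ± 0.278 and 28.0 ± 0.631 CPM. Transcripts of both sex chromosomes were present in each arm: the Y-linked Ddx3y was at 26.3 ± 0.547 and 90.7 ± 3.31 CPM, Eif2s3y at 26.4 ± 1.66 and 111 ± 5.33 CPM, Uty at 7.92 ± 0.215 and 33.8 ± 1.72 CPM. Kdm5d, also Y-linked, was 2.62-fold higher, and Xist, the RNA of X inactivation, was at 103 ± 3.69 and 189 ± 11.5 CPM. Their X-linked relatives Ddx3x, Eif2s3x and Kdm5c fell 1.47-fold, 2.34-fold and 1.86-fold. Among genes above a mean of 5 CPM, the 74 long intergenic noncoding genes had a median log2 fold change of 0.72 and the 9434 protein-coding genes one of -0.13. The median was 0.78 for 55 processed transcripts, 0.65 for 54 antisense genes and 0.069 for 117 processed pseudogenes, and the differences between classes were not tested.

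Genes of the held-out cell cycle lists moved with the first lists: 29 of 30 tested S phase genes fell and 1 rose, with a median log2 fold change of -1.53, and 28 of 29 G2/M genes rose and 1 fell, with a median of 1.04. The base excision enzyme gene Ung fell from 124 to 8.97 CPM, and Psrc1, a spindle-associated gene, rose from 1.28 to 49.6 CPM and Cdc25b, a phosphatase of mitotic entry, from 24.5 to 140 CPM. Tk1, a thymidine kinase usually counted with S phase, was the S phase exception, at 14.7 and 16.2 CPM, and Bub3, a checkpoint gene, was the G2/M exception, at 137 and 98.4 CPM.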
